A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

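RNA of 2 Saccharomyces cerevisiae strains of the W303 background was compared on 3 two-colour DNA microarrays. Both strains carried WAR1 behind the galactose-inducible GAL1 promoter, in 1 strain as War1 and in the other as War1K762R, whose name gives an exchange of lysine for arginine. Per the labels' protocols, cultures grew in rich medium with 2% raffinose at 30 °C to an OD600 of 0.8, received 2% galactose and were harvested after 1 h. RNA was extracted with hot phenol, and 20 µg of total RNA was copied into cDNA with Cy3 or Cy5 nucleotides, per the labels' protocols. Each array held 1 culture of each strain, and the design text calls all 3 arrays biological repeats. War1K762R was in Cy5 on replicates 1 and 2 and in Cy3 on replicate 3, the dye swap. These orientations come from the source names of the channels. The treatment text of the Cy3 channel of replicates 1 and 2 names the mutant instead, which would put the mutant in both channels, and was not used.

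The authors deposited 1 log2 ratio per spot and array. The scanner, the ratio formula, the spot filter and the normalization are not given in the sources used here, and no intensities or backgrounds were used here. The log2 base and the direction of the deposited values were read from their rounding. Among values between −0.5 and 0.5, 2 to the power of the value was a number with 3 decimals, within what the rounding of the logarithm to its last printed decimal allows, for 100% of 9077 values of replicate 1 and of 9945 values of replicate 2. In replicate 3 this held for 11.7% of 6685 values, against 8.77% by chance, but for 100% after a change of sign. The column of replicate 3 was therefore taken as inverted before deposit, so that all 3 columns ran the same way. That this way is War1K762R over War1 rests on the dye labels and on the assumption that the scanner's ratio was Cy5 over Cy3. No source used here states that formula, so the direction is likely and not certain. If it was Cy3 over Cy5, every sign in the text turns, and the counts, sizes and tests stay. The plan written before the data were examined took the columns as Cy5 over Cy3 and turned replicate 3 by its dye label. Turning the recovered scanner ratio of replicate 3 in this way returns the deposited value, so this fit and the fit to values taken as already turned, also fixed beforehand, are the same. Applied to the columns as deposited, without the evidence of the rounding, the written plan turns the sign of replicate 3 once more and calls 0 genes (limma, 145 at an unadjusted p under 0.05). The rounding was examined in the same first look as the correlations of the arrays and the values of PDR12 and ATO2.

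The table held 13056 spots. The platform annotation gave 1 gene symbol for 11146 spots, several for 0 and none for 1910. The named spots belonged to 5543 genes, 5514 of them with 2 spots and 29 with more. Of the 5543 gene identifiers, 5538 were found in the reference gene table of the R64 assembly, and 0 symbols needed an update. The array's genome build is not given in the sources used here, so the reference table served for names and neighbouring genes and no coordinates are printed. Values were present for 12277 spots of replicate 1, 12112 of replicate 2 and 7367 of replicate 3, so that 6.0%, 7.2% and 43.6% were missing. The rule that removed them is not given in the sources used here. The medians of the columns as deposited were −0.27, 0.16 and 0.09 on the log2 scale, so the arrays had not been centred on 0. Across genes with 2 measured spots, the spots of a pair correlated with Pearson's r of 0.883, 0.763 and 0.731, and the SD of a single spot was 0.12, 0.17 and 0.14 on the log2 scale. The number of arrays limits the precision.

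Each array was centred on the median of all its spots, spots of one gene were averaged within an array, and the 3579 genes with a value on all 3 arrays were tested. The mean log2 ratio was tested against 0 with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over these genes and a threshold of adjusted p 0.05. Every adjusted p in the text is from limma. Errors are the SD between arrays, n = 3. Genes at least 1.5-fold apart on the same side in all 3 arrays were counted without a test. Gene lists written before the data were examined, 26 with 927 genes, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 25 lists with at least 5 measured genes. Camera compares a list with all other genes tested, whose median mean ratio was 0.05 and not 0. For genes on at least 2 arrays, where values are missing, limma's cameraPR on the moderated t statistics took its place, at the same preset correlation. The list of auxotrophic markers of W303 had 3 measured genes and was not tested. Camera with an estimated correlation and fry were alternatives. Both rest on the few residual degrees of freedom of 3 arrays, so they could hardly pass any list. With an estimated correlation the lowest adjusted p of a list was 0.809 (camera). The estimate was −0.07 for galactose genes and 0.02 for ribosome biogenesis, against 0.65 for ribosomal proteins. Not passing there therefore does not by itself show that correlation between genes ended a call. Fry tests a list against no change and not against other genes, so its counts and directions answer another question. Correlations between arrays were taken across genes, which are not independent replicates, and carry no p-value.

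The rule for named genes was fixed before the data were examined. It took WAR1, PDR12 and FUN34 (ATO2 in the annotation), and the 10 highest and 10 lowest means among genes past the threshold with one sign in all 3 arrays, filled from genes that did not pass. It also took up to 4 passing members of each list, or the 2 largest means where none passed. List members outside this rule that are named because they passed adjusted over the list alone, such as GAL1, GAL2, GAL3, GAL7, GAL80, PGM2, JEN1, ACH1, FTR1, ICT1, PDR5 and SSA1, were chosen after their values were seen, as were TAL1, YGR067C and the further genes of the closing section.

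Alternatives fixed beforehand were the values as already turned, a dye term, no centring, scaling to one median absolute deviation, genes on at least 2 arrays, each spot on its own, robust eBayes, array weights, each replicate left out, an adjusted p of 0.10 and a 2-fold limit. With each spot on its own, the spots of one gene entered a list as separate members, although they correlated within arrays. List calls on single spots therefore count a gene more than once and pass too easily. For a named gene in that setting, the mean over its spots is given with the lowest adjusted p among them. A named gene thus passed there if at least 1 of its spots did. Replicate 3 turned once more, centring on a running median over 401 spots, centring on the median of the genes tested, and leaving out replicate 3 on the same genes were added after seeing the data. The fit was tested on simulated ratios for 3579 genes with 200 changed genes. It called 34% of the genes simulated at a log2 change of 0.5, 96% at 1, and 100% at 1.5 and at 2. Of its 169 calls, 4 were false, and 0 of the changed genes were called with the wrong sign. With so many changed genes the adjusted threshold is easier to pass than in the real data, where 13 genes passed. The simulated noise was independent between genes, with no shared array or dye effect. The shares called therefore do not give the power of the real fit. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.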

Results

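Transcript levels were measured on 3 two-colour arrays, each of which set a culture producing War1K762R directly against a culture producing War1. War1 is the zinc cluster transcription factor that induces the transporter gene PDR12 under weak organic acid stress. Both forms were made from the GAL1 promoter for 1 h in galactose, with no acid named in the labels. A spot had a value on 12277, 12112 and 7367 of 13056 spots in replicates 1, 2 and 3, and 3579 genes were measured on all 3 arrays. Ratios are given as War1K762R over War1, a direction that is likely and rests on the dye labels and on a scanner ratio of Cy5 over Cy3, which no source used here states. The median SD of a gene between the 3 arrays was 0.20 on the log2 scale. Across genes the ratios correlated weakly, with Pearson's r of 0.311 for replicates 1 and 2, 0.179 for 1 and 3, and 0.252 for 2 and 3 (Spearman's rho 0.305, 0.155 and 0.236).

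The design asks which transcripts differ between cells with War1K762R and cells with War1. Both War1 target genes fixed for naming beforehand rose with War1K762R. ATO2 (YNR002C, also FUN34), which encodes a plasma membrane protein of the acetate and ammonium transporter family, was 3.63-fold higher (mean log2 ratio 1.86 ± 0.76, SD, n = 3, adjusted p = 0.0139). PDR12 (YPL058C), the ABC transporter that expels carboxylate anions, was 1.95-fold higher (0.96 ± 0.45, adjusted p = 0.0461). Both were higher on all 3 arrays, ATO2 with log2 ratios of 2.60, 1.90 and 1.08 and PDR12 with 1.41, 0.95 and 0.52 in replicates 1, 2 and 3. WAR1 itself (YML076C) had a mean of 0.35 ± 0.34 and did not pass the test (adjusted p = 0.32), with 0.74, 0.12 and 0.19 on the arrays. Its spots read the transcripts of both forms and so check no label. The call of PDR12 ended without replicate 1 (0.73, adjusted p = 0.181) and with a dye term (0.85, adjusted p = 0.105). It also ended on single spots (mean 0.96, lowest adjusted p of its spots 0.0509) and with centring on the genes tested (0.92, adjusted p = 0.103). ATO2 passed in all of these, and neither gene passed with replicate 3 turned once more (adjusted p = 0.902 for both).

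In all, 13 of 3579 genes passed, 12 higher and 1 lower with War1K762R, and 493 genes had an unadjusted p under 0.05, 397 of them higher. Of the metabolic genes that rose, BDH2 (YAL061W), a putative alcohol dehydrogenase gene, was 3.26-fold higher (1.71 ± 0.70, adjusted p = 0.0139). CAR1 (YPL111W), which encodes arginase, was 2.02-fold higher (1.02 ± 0.45, adjusted p = 0.0378). CIT3 (YPR001W), a mitochondrial citrate and methylcitrate synthase gene, was 2.01-fold higher (1.01 ± 0.40, adjusted p = 0.0375). ALD4 (YOR374W), which encodes mitochondrial aldehyde dehydrogenase, and UGA1 (YGR019W), which encodes 4-aminobutyrate transaminase, were 1.82- and 1.81-fold higher (0.86 ± 0.28, adjusted p = 0.0378, and 0.86 ± 0.25, adjusted p = 0.0375). GAL10 (YBR019C), of galactose use, was 1.90-fold higher (0.93 ± 0.11, adjusted p = 0.0139). TPO4 (YOR273C), a polyamine exporter gene, and UBX2 (YML013W), of protein quality control at the endoplasmic reticulum, were 1.75- and 1.73-fold higher (0.81 ± 0.11, adjusted p = 0.0363, and 0.79 ± 0.27, adjusted p = 0.0461). TAL1 (YLR354C), the transaldolase gene, and YGR067C, a putative zinc finger gene, were named after their values were seen, at 0.79 ± 0.26 and 0.69 ± 0.08 (adjusted p = 0.0461 for both). Without replicate 1 the calls of these 10 genes ended, with adjusted p from 0.0551 for BDH2 to 0.194 for TAL1, while their mean ratios over the other arrays were 1.79 for BDH2, 0.91 for GAL10, 0.85 for ALD4 and UBX2 and, lowest of the 10, 0.69 for TAL1. The weakest of the 13 calls were TPO4, UBX2 and YGR067C, which passed in 8, 6 and 5 of 13 other settings. All 3 calls ended with a dye term (adjusted p = 0.0942, 0.129 and 0.118), on single spots (0.0509, 0.0509 and 0.0589) and with centring on the genes tested (0.0709, 0.103 and 0.104). With a dye term the means of TPO4 and UBX2 were 0.78 and 0.74. Over the 13 settings the means of TPO4, UBX2 and YGR067C ranged from 0.75 to 0.87, 0.64 to 0.89 and 0.65 to 0.74.

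The 1 gene that fell was UIP5 (YKR044W), whose product was found to bind the SUMO protease Ulp1. It was 3.03-fold lower with War1K762R (mean −1.60 ± 0.22, adjusted p = 0.000751), with −1.60, −1.82 and −1.38 on the arrays. The next lowest means on one side of 0 in all 3 arrays did not pass: CMS1 at −0.64, YLR161W at −0.52, YLR159W at −0.51, OM45 at −0.49, MET16 at −0.48, and MMS4, IMP3, RPL36A and ATP23 at −0.45 each. Without a spread estimate, 7 genes were at least 1.5-fold higher and 1 at least 1.5-fold lower on all 3 arrays. Over the 2 arrays left without replicates 1, 2 and 3 in turn, the higher count was 19, 10 and 50 and the lower count 2, 1 and 46. Without replicate 3 on the same genes the counts were 46 and 3. All 3 arrays gave one sign for 1369 genes, 885 of them positive, where chance gives 25% of 3579 for ratios split evenly about 0. After centring on all spots the genes tested had medians of 0.0708, 0.0571 and 0.0055 in replicates 1, 2 and 3. That offset favours positive signs, also among the 397 genes higher at an unadjusted p under 0.05 (limma). The number of genes that rose went from 12 to 1 without replicate 1, to 29 without replicate 2, to 46 without replicate 3 (15 on the same genes), to 2 with a dye term and to 3 with centring on the genes tested. The number that fell was 34 without replicate 3 (1 on the same genes) and stayed at 1 in the other settings of this comparison. The count of 29 rests on p-values that take little account of a gene's own spread. ATO2, with 2.60 and 1.08 on the arrays left, had an adjusted p of 2.54e-19 there (limma). With replicate 3 turned once more, which is the written plan applied to the columns as deposited, 0 genes passed in limma and 145 had an unadjusted p under 0.05.

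**Figure D1:**
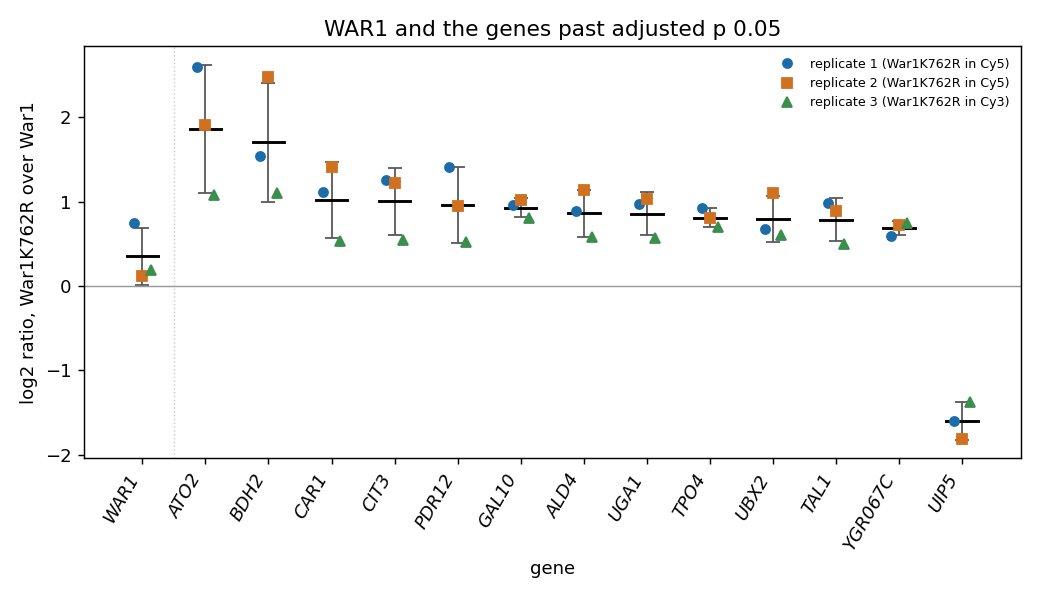
Log2 ratios of War1K762R over War1 for WAR1 and the 13 genes past adjusted p 0.05; symbols are the 3 arrays, black bars the means and whiskers the SD between arrays (n = 3). ATO2 lies between 1.08 and 2.60 and UIP5 between −1.82 and −1.38, while WAR1 lies between 0.12 and 0.74.

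The list of galactose genes had 11 measured genes with a median of 0.39 and passed as higher than other genes at the preset correlation (camera, adjusted p = 0.000761), but not with an estimated correlation (adjusted p = 0.809) or with replicate 3 turned once more (adjusted p = 0.494). Its array medians were 0.46, 0.31 and 0.35. Over all genes 1 member, GAL10, rose and 0 fell; adjusted over the list alone, 7 rose. Besides GAL10 these were, named like the members of other lists that passed over the list alone after their values were seen, the permease gene GAL2 at 0.60 ± 0.19, the galactokinase gene GAL1 at 0.59 ± 0.49, and the regulator gene GAL3 at 0.71 ± 0.23, with GAL7, GAL80 and PGM2 at 0.50, 0.32 and 0.39. GAL1 shares with GAL10 the intergenic promoter region that drove WAR1 here.

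Genes of glycolysis and fermentation lay higher than other genes as a list (27 measured, median 0.20, camera, adjusted p = 0.00621, and adjusted p = 0.901 with an estimated correlation). Of its members 0 passed, over all genes or adjusted over the list alone; ADH5 had a mean of 0.63 ± 0.83 and PFK2 of 0.48 ± 0.55. Gluconeogenesis, the glyoxylate cycle and acetate use had 25 measured genes and a median of 0.18 (adjusted p = 0.0352, and adjusted p = 0.901 with an estimated correlation). ATO2 and ALD4 rose, and adjusted over the list alone so did JEN1 and ACH1, which encode the lactate and pyruvate permease and acetyl-CoA hydrolase (0.83 ± 0.43 and 0.50 ± 0.24). Iron and copper uptake had 20 measured genes and a median of 0.22 (adjusted p = 0.0123, and adjusted p = 0.901 with an estimated correlation). Over all genes 0 of these passed, and 3 did adjusted over the list alone, the cell wall mannoprotein gene FIT1 at 0.75 ± 0.33, the copper transporter gene CCC2 at 0.63 ± 0.34 and the iron permease gene FTR1 at 0.50 ± 0.26. Without replicate 2 the calls of glycolysis and of iron and copper ended (adjusted p = 0.324 and 0.282), and that of gluconeogenesis ended without replicate 1 (0.752) and with array weights (0.0699). With replicate 3 turned once more the calls of gluconeogenesis and of iron and copper ended (adjusted p = 0.152 and 0.412). Glycolysis still passed as higher in that setting (camera, adjusted p = 0.00101), so the dye swap does not separate strain from dye for this list. Its array medians in the main fit were 0.23, 0.40 and 0.04.

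Over the 3 arrays together, lists of ribosome genes tested lower than other genes at the preset correlation, by small amounts. For 128 ribosomal protein genes the median was −0.05, against 0.05 for all genes tested (camera, adjusted p = 7.35e-06, and adjusted p = 0.901 with an estimated correlation), and 0 passed, over all genes or adjusted over the list alone. RPL36A and RPL19B had means of −0.45 ± 0.18 and −0.38 ± 0.13. The array medians of this list were 0.13, −0.04 and −0.28, so the sign differed between arrays. In replicate 1, where the genes tested had a median of 0.07, the list lay higher. Without replicate 3 its direction turned to higher (adjusted p = 0.456), and it was lower but did not pass on the same genes (adjusted p = 0.343). With replicate 3 turned once more it passed as higher (adjusted p = 0.000439). For 71 ribosome biogenesis genes the median was −0.07 (adjusted p = 0.000125, and adjusted p = 0.809 with an estimated correlation), with array medians of −0.22, −0.06 and −0.04. With replicate 3 turned once more these genes still passed as lower as a list (camera, adjusted p = 0.00288). The dye swap therefore does not separate strain from dye for them. Of these genes 0 passed, over all genes or adjusted over the list alone; IMP3 had a mean of −0.45 ± 0.07 and KRR1 of −0.41 ± 0.28.

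The list of weak acid response and carboxylate transport had 18 measured genes and did not pass (median 0.22, adjusted p = 0.0659). Its array medians were −0.002, 0.39 and 0.17. Of the 18 genes 5 were positive and 1 negative on all 3 arrays, where 24.7% of all genes tested were positive on all 3. Of its members ATO2 and PDR12 rose, and adjusted over the list alone JEN1 did as well. The list passed as higher without replicates 1, 2 and 3 in turn (adjusted p = 0.0142, 0.00182 and 0.00807), without centring (3.19e-05), on at least 2 arrays (0.0195), on single spots (0.00871) and with array weights (0.0445). It did not pass with an estimated correlation (adjusted p = 0.901) or with replicate 3 turned once more (adjusted p = 0.152). Among 21 genes of pleiotropic drug resistance and ABC transporters, PDR12 and TPO4 rose (list adjusted p = 0.167). Adjusted over the list alone, the lipid acyltransferase gene ICT1 at 0.63 ± 0.09 and the multidrug transporter gene PDR5 at 0.61 ± 0.57 rose too. This list passed as higher on single spots (adjusted p = 0.0298), but not with an estimated correlation (adjusted p = 0.901).

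The other 17 lists did not pass and held 0 genes past the threshold over all genes. General stress genes had a median of 0.19 (45 measured, adjusted p = 0.107). That list passed as higher without replicate 3 (adjusted p = 3.37e-05, and 0.00243 on the same genes), on at least 2 arrays (0.0064), on single spots (0.0298), with array weights (0.0492) and with replicate 3 turned once more (0.000257). It did not pass with an estimated correlation (adjusted p = 0.901). Adjusted over the list alone, 4 rose, among them the chaperone gene SSA4 at 0.60 ± 0.43 and the trehalose phosphatase gene TPS2 at 0.60 ± 0.27, and OM45, of the mitochondrial outer membrane, fell at −0.49 ± 0.08. Of 30 chaperone genes (adjusted p = 0.388), 3 rose adjusted over the list alone, HSP60 at 0.56 ± 0.17, SSA1 at 0.53 ± 0.27 and SSA4. In methionine and sulfur metabolism (26 measured, adjusted p = 0.785), CYS4 at 0.63 ± 0.22 rose and MET16 at −0.48 ± 0.09 fell adjusted over the list alone. That list tested lower than other genes although its median was 0.07. In 4 further lists 1 gene each rose adjusted over the list alone: the fatty acid activation gene FAA4 at 0.50 ± 0.18 for peroxisomes and fatty acid oxidation (14 measured, adjusted p = 0.318), the phosphatase gene PHO8 at 0.54 ± 0.19 for the phosphate response (21, adjusted p = 0.718), the ribonucleotide reductase gene RNR4 at 0.71 ± 0.45 for the cell cycle (28, adjusted p = 0.388), and YJR028W at 0.61 ± 0.11 for retrotransposons and subtelomeric families (41, adjusted p = 0.388), a family of near-identical copies whose cross-hybridisation was not checked. Without replicate 3 the lists of chaperones, peroxisomes and retrotransposons passed as higher (adjusted p = 0.0247, 0.02 and 0.00364). They did not pass on the same genes (adjusted p = 0.132, 0.321 and 0.0586) or with an estimated correlation (0.901, 0.901 and 0.923). Peroxisomes and retrotransposons also passed on at least 2 arrays (adjusted p = 0.0196 and 0.0366), and retrotransposons with replicate 3 turned once more (0.0142).

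In the remaining 10 lists 0 genes passed even adjusted over the list alone. For respiration and the tricarboxylic acid cycle (53 measured, adjusted p = 0.844) the largest means were ATP1 at 0.54 and CYB2 at 0.51. For amino acid biosynthesis other than methionine (58, adjusted p = 0.2) they were BAT2 at 0.60 and LEU1 at 0.57. Ergosterol synthesis (23, adjusted p = 0.107) had HMG1 at 0.51 and ERG26 at 0.39, oxidative stress (33, adjusted p = 0.438) TRR1 at 0.43 and SOD2 at 0.36, and the zinc response (10, adjusted p = 0.438) COT1 at 0.30 and ZRT1 at 0.26. Cell wall genes (39, adjusted p = 0.589) had SCW4 at 0.55 and SPI1 at 0.41, mating genes (16, adjusted p = 0.924) STE2 at 0.26 and AGA1 at 0.25, and the vacuolar ATPase (15, adjusted p = 0.877) VMA5 at 0.42 and VMA2 at 0.34. Histone genes (10, adjusted p = 0.107) had HHF2 at −0.21 and HHF1 at −0.19, and the proteasome (34, adjusted p = 0.064) PRE8 at 0.39 and PRE6 at −0.28. Without replicate 3 respiration, amino acid biosynthesis, ergosterol synthesis, oxidative stress and the cell wall passed as higher (adjusted p = 0.00373, 0.0109, 0.0126, 0.00243 and 0.021), of which ergosterol synthesis and oxidative stress passed on the same genes (0.0287 for both). On at least 2 arrays amino acid biosynthesis, ergosterol synthesis and the cell wall did (adjusted p = 0.0199, 0.0427 and 0.0366), and with replicate 3 turned once more respiration, ergosterol synthesis and oxidative stress (0.00302, 0.0217 and 0.000439). Ergosterol synthesis also passed without replicate 1 (adjusted p = 0.0142), on single spots (0.0242) and with array weights (0.0329). It did not pass with an estimated correlation (adjusted p = 0.901), and its direction turned to lower without replicate 2 (0.864). Histones passed as lower without replicate 1 (adjusted p = 0.00373), with a dye term (0.0292) and on single spots (0.022). They did not pass with an estimated correlation (adjusted p = 0.901), and their direction turned to higher without replicate 3 (0.698). Their array medians were 0.24, −0.13 and −0.29. The proteasome passed as lower without replicate 1 (adjusted p = 0.0413), on single spots (0.0107), with array weights (0.0457) and with a running median (0.0456). It did not pass with an estimated correlation (adjusted p = 0.901).

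**Figure D2:**
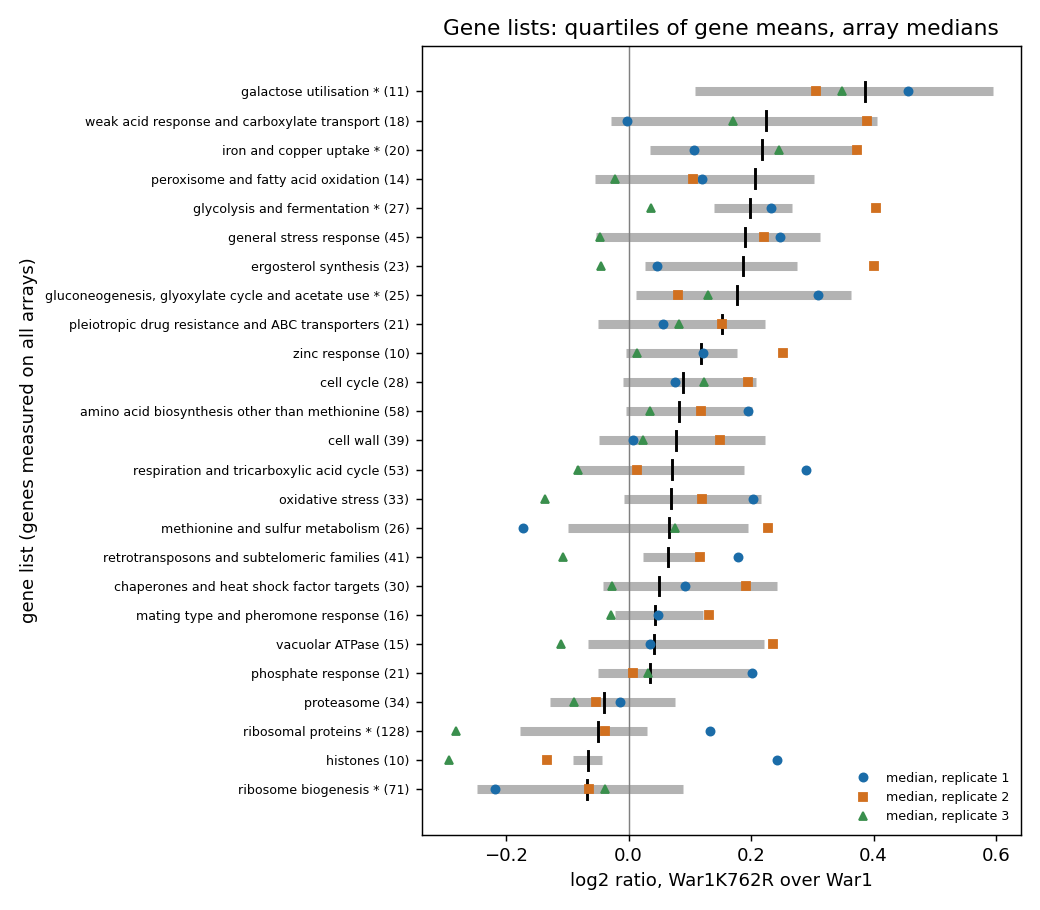
Gene lists with the number of measured genes in brackets, against the log2 ratio of War1K762R over War1. Grey bars span the quartiles of the gene means, black lines are their medians, symbols are the medians on each of the 3 arrays, and stars mark the 6 lists past adjusted p 0.05 by camera, 0 of which passed with an estimated correlation; the galactose list lies between 0.31 and 0.46 on all 3 arrays.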

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

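Replicate 3 turned once more, centring on a running median or on the genes tested, and leaving out replicate 3 on the same genes were chosen after seeing the data. Values read as already turned gave the same fit and move nothing. Signal over background was not used here, so what it limits is unknown, and robust eBayes was not run for lists. With replicate 3 turned once more all 13 calls ended. Over the 13 settings besides that one and the already turned values, ATO2 and UIP5 passed in 13, BDH2 in 12, GAL10 in 11, CIT3 in 10, ALD4, CAR1, PDR12, TAL1 and UGA1 in 9, TPO4 in 8, UBX2 in 6 and YGR067C in 5, with one sign throughout. Without centring and without replicate 2, ATO2 had adjusted p of 1.45e-16 and 2.54e-19 (limma). Values that small from so few arrays mean that the variance was pooled almost wholly over genes. Passing in these settings therefore says little of a gene's own spread between arrays. Over all named genes and settings a call was lost 59 times and gained 21 times. Over lists a call was lost or turned 22 times and gained 44 times. Causes were not tested except where fewer arrays, other genes or another threshold show them.

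The 12 genes higher and 1 lower became 2 and 1 with a dye term, 25 and 1 without centring, and 67 and 50 of 5479 genes on at least 2 arrays. On single spots 7 and 2 of 6852 spots passed, which are not counts of genes. Of the 13 called genes, 5 passed there with at least 1 spot. The gene counts were 24 and 1 with array weights, 19 and 1 with a running median, 3 and 1 with centring on the genes tested (75% higher against 92.3%) and 33 and 1 at adjusted p 0.10. With each replicate left out they ranged from 1 to 46 and from 1 to 34, the highest of 5475 genes without replicate 3. With replicate 3 turned once more 0 passed on each side (limma, 145 at unadjusted p under 0.05), and the 1.5-fold counts were 1 and 0. The 7 genes at least 1.5-fold higher and 1 lower became 13 higher without centring, 11 and 44 on at least 2 arrays, and 2 higher at 2-fold. With a replicate left out they ranged from 10 to 50 and from 1 to 46. Without replicate 3 on the same genes they were 46 and 3. On single spots, where the spots of a gene count separately, 18 spots were higher and 2 lower.

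The 6 lists became 13 on at least 2 arrays, with cameraPR and more genes. With a replicate left out they ranged from 5 to 15, and with replicate 3 turned once more 8 passed. They became 12 on single spots, where the spots of one gene count as separate members. With an estimated correlation, which rests on few residual degrees of freedom, 0 passed. Fry, which tests against no change and not against other genes, passed 0 lists. The correlation of replicates 1 and 2 was 0.394 on all genes of that pair. With replicate 3 turned once more, signs turned for YLR159W (0.0096), STE2 (−0.0871), HHF2 (0.11) and HHF1 (0.17), and directions for ribosomal proteins (adjusted p = 0.000439), histones (0.198) and the cell cycle (0.99). Directions that passed in neither setting turned with a dye term for respiration (adjusted p = 0.728), methionine (0.983), mating (0.981) and vacuolar ATPase (0.981), for mating without centring and on single spots (0.917 each), and on at least 2 arrays for methionine (0.899) and mating (0.256). Fry gave methionine as higher than no change (0.685), where camera gave it as lower than other genes. With a replicate left out, adjusted p ranged, with at least 1 turn of direction, from 7.13e-14 to 0.456 for ribosomal proteins, 0.0247 to 0.969 for chaperones, 0.00373 to 0.511 for respiration, 0.246 to 0.776 for methionine, 0.0126 to 0.864 for ergosterol, 0.00243 to 0.845 for oxidative stress, 0.021 to 0.871 for cell wall, 0.334 to 0.917 for mating, 0.00373 to 0.698 for histones and 0.229 to 0.746 for vacuolar ATPase.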

Other observations

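The tests of chance over all genes, of the dyes, of the WAR1 transcript and of UIP5, and the genes in the next 2 paragraphs apart from the W303 markers, were chosen after the result was seen.

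Single genes related to those that rose are given as values, with no test of them as a group; 24.7% of all genes tested were positive on all 3 arrays. Next to the arginase gene CAR1, the ornithine transaminase gene CAR2 had a mean log2 ratio of 0.46 ± 0.12 (SD, n = 3, adjusted p = 0.134), and PUT1 and PUT2, of proline use, had 0.55 ± 0.28 and 0.35 ± 0.15 (adjusted p = 0.123 and 0.259). The repressor gene DAL80 had 0.56 ± 0.30 (adjusted p = 0.123) and the permease gene GAP1 0.26 ± 0.03 (adjusted p = 0.364). Next to UGA1, UGA2 had 0.08 ± 0.16 (adjusted p = 0.802), and the permease gene UGA4 had −0.02 and −0.28 in replicates 1 and 2 and no value in replicate 3. Next to CIT3, the 2-methylisocitrate lyase gene ICL2 had 0.74 ± 0.35 (adjusted p = 0.0719) and PDH1, of the same propionate breakdown route, −0.15 ± 0.05 (adjusted p = 0.583). BDH1, the neighbour and relative of BDH2, had 0.05 ± 0.01 (adjusted p = 0.872). The nicotinic acid permease gene TNA1 had 0.88 ± 0.47 (adjusted p = 0.0648), and THI7 and NRT1, near-identical copies whose cross-hybridisation was not checked, had 0.71 ± 0.32 and 0.74 ± 0.27 (adjusted p = 0.0719 and 0.0575). Of the genes in this paragraph, ICL2, TNA1, THI7 and NRT1 passed among the 5479 genes on at least 2 arrays (adjusted p = 0.0243, 0.0145, 0.0246 and 0.0155).

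The relatives of ATO2 differed between arrays: ADY2 had 1.35, −0.62 and −0.41 and ATO3 1.45, −0.61 and 0.36 in replicates 1, 2 and 3. The fatty acid oxidation gene POX1 had a mean of 1.51 ± 0.02 over replicates 1 and 2 and no value in replicate 3. DCI1, of the same pathway, had 0.87 and 0.97 there, and the peroxisomal transporter gene PXA1 1.03 and 0.51. Among the genes on at least 2 arrays POX1, DCI1 and PXA1 passed (adjusted p = 0.000444, 0.0133 and 0.0438), from 2 arrays of one dye orientation, and without replicate 3 POX1 and DCI1 passed and PXA1 did not (0.000928, 0.0154 and 0.0504). Among the markers of W303, LEU2, URA3 and CAN1 were measured on all 3 arrays, with means of 0.04, −0.11 and 0.24, and ADE2, HIS3 and TRP1 had −0.09, −0.26 and −0.05 over replicates 1 and 2. Of 476 spots without a gene name that had a value on all 3 arrays, 0 passed in limma and 45 had an unadjusted p under 0.05.

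Turning the sign of 1 array at a time gives 4 sign patterns of the 3 arrays, too few for a share under 0.05. The real orientation called 13 genes and the highest of the other patterns 0, so that 1 of the 4 patterns gave as many. For gene lists, the real orientation gave 6 and the highest other pattern 8, with 3 of the 4 patterns giving at least as many. The pattern with 8 turned replicate 3, which lines the arrays up by dye and not by strain. The number of lists therefore does not separate a strain difference from a dye effect.

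ATO2, PDR12 and 10 other genes were higher with War1K762R. A dye bias as the whole effect would turn in the swapped array, but of 46 genes at least 1.5-fold higher in both replicates 1 and 2, 43 were positive in replicate 3 as well, or 93.5% (exact 95% interval 82.1% to 98.6%), against 51% of all genes tested. This holds only for the direction of replicate 3 read from the rounding, since with that array turned once more 3 of the 46 (6.5%) would be positive, and the interval takes genes as independent. The median of the 46 genes in replicate 3 was 0.34. A dye part smaller than the strain difference would keep the sign, so it stays open. More WAR1 transcript in the War1K762R cultures, perhaps from a stronger galactose response, may account for part of the change. WAR1 had a mean log2 ratio of 0.35 (limma's 95% interval 0.03 to 0.68), which did not pass (adjusted p = 0.32) and was 0.16 without replicate 1. The galactose list, with a median of 0.39, passed as higher without replicates 1, 2 and 3 in turn (camera, adjusted p = 0.000502, 0.000282 and 0.00127) and with a dye term (0.00095). It did not pass with an estimated correlation (adjusted p = 0.809), a test that could hardly pass any list. Beside WAR1 at 0.16 without replicate 1, ATO2 and PDR12 had means of 1.49 and 0.73 in that setting. How their levels scale with WAR1 transcript is not known here. An effect of the amino acid exchange itself cannot be told apart from more WAR1 transcript, since no array compares the forms at known equal amounts of it.

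Genes with no value in replicate 3 leaned low in replicates 1 and 2, with medians of −0.15 and −0.12 over 1890 genes, and without replicate 3 as a requirement 48 of the 50 genes called lower had no value there. A candidate explanation is that dim spots lean towards Cy3, which held War1 in replicates 1 and 2 and War1K762R in replicate 3. The 304 genes with 1 of 2 spots measured in replicate 3 lay 0.14 and 0.12 below the 3252 genes with both in replicates 1 and 2, and 0.12 above them in replicate 3 (95% bootstrap interval 0.09 to 0.17), which is consistent with that lean. These genes were picked by the spot filter of replicate 3, whose rule is unknown and may itself have selected high ratios there. The lean, that selection and transcripts truly lower with War1K762R therefore cannot be told apart.

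UIP5 was the only gene of the 3579 tested that passed as lower, and it passed in 13 of 13 settings besides replicate 3 turned once more (−0.68, adjusted p = 0.902). A failed spot is argued against by its 2 spots, which differed by at most 1.12 SDs of a single spot on any array and were all low on every array. Loss of the surrounding chromosome segment is argued against by the 3 measured genes on either side, whose median mean ratio was 0.0535 (from −0.13 to 0.21). A misplaced or wrongly named probe, whose copies would agree as well, a difference between the strains at UIP5 itself from their construction, and an effect of War1K762R stay open and were not tested.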
